A study of Mus musculus with 6 samples.

How the data were processed

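The deposited table gives, for 23390 mouse genes, counts and FPKM in 6 libraries of sorted small-intestinal epithelial cells, 3 from Maf.flox and 3 from Vil.Cre Maf.flox mice. Per the labels' protocols, total RNA was purified, mRNA was captured on poly-T beads and reverse transcribed with random hexamers, and the protocol leaves open whether the libraries kept strand. Per the submitters' processing notes, HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 were used with the GRCm38 (mm10) build. The counts deposited by the authors are whole numbers, not normalised. The FPKM values deposited by the authors equal the count divided by gene length and by a single library size per library, which was between 0.953 and 1.07 times the summed counts. FPKM values were checked in this way and not tested. Of the gene identifiers, 23383 were also in GENCODE M21 (GRCm38), 97.01% of them with the same start and end. A spreadsheet had turned 24 gene symbols into dates, and these were restored by identifier.

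Counts were tested with edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr (least count 10), libraries scaled by TMM, and genotype tested by the quasi-likelihood F test with robust estimation and Benjamini-Hochberg adjustment over 13740 genes. No batch, litter or sex was labelled, so genotype was the only term. Values are TMM-normalised CPM (counts scaled to library size), and scores use log2 CPM with a prior count of 2. Of the 32 gene lists, fixed with the tests before the data were examined, each was tested with camera (limma 3.58.1, preset correlation 0.01, two-sided), with camera at an estimated correlation, and with fry; members were also adjusted over the list alone. Genes were named by a rule fixed at the same time: Maf family members; the 12 largest rises and 12 largest falls among called protein-coding genes with a mean of at least 50 normalised counts in the higher group and no overlap between libraries; the 4 members of each list with the smallest p; and, for cells the sort should exclude, also the highest members. Some genes that this rule takes are not reported here.

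Alternatives were other scaling factors (RLE, upper quartile), no filter and a stricter filter, DESeq2 1.42.0, limma-voom, other FDR thresholds, a replicate block and each library left out. A term for sex, which Xist and Y-linked counts gave, and other edgeR dispersion settings were chosen after seeing the data. A pseudocount alternative did not apply to counts. The 10 groupings of the libraries into 3 and 3 were each tested. Replicate pairs within a group differed far beyond counting noise (chi-square per gene 35.2 to 133), so no library was a copy of another.

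The tests were checked on simulated counts for this comparison over 13740 genes. EdgeR recovered 65% of genes changed 2-fold and 95% of those changed 4-fold, and 5.9% of its calls were false. DESeq2 recovered 73% and 96% with 15.5% false calls, and limma-voom 66% and 94% with 5.3%. The counts were drawn from edgeR's own dispersion estimates, with independent genes and no deviating library. Recovery and error rates in the real libraries can therefore differ. In these, not every gene with a change beyond 4-fold was called, such as Cyp2b10 with a log2 fold change of -3.53. A gene that was not called may thus still have changed. Camera found the planted list, but the simulated genes varied independently, which real genes do not, so this check says nothing on its error rate in correlated lists. With 17464355 to 24802525 counts per library, 1 CPM is 17.5 to 24.8 counts.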

Results

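RNA was sequenced from small-intestinal epithelial cells of C57BL/6 mice, sorted as living cells that lacked the leukocyte marker CD45 and carried the epithelial marker EpCAM. There were 3 libraries from mice in which Cre, driven by the villin promoter, removes floxed Maf from the intestinal epithelium (Vil.Cre Maf.flox) and 3 from floxed controls without Cre (Maf.flox). Total counts were 24802525, 19842751 and 20401492 in Maf.flox replicates 1, 2 and 3, and 20051246, 17464355 and 21631476 in Vil.Cre Maf.flox replicates 1, 2 and 3. Counts of Xist and of Y-linked genes placed 1 male and 2 females among the controls and 2 males and 1 female among the Vil.Cre Maf.flox mice, so sex was not balanced. The labels do not state that each library came from a separate mouse or preparation day, and p-values measure the spread between these libraries.

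The comparison of Vil.Cre Maf.flox with Maf.flox addresses what loss of c-Maf, a basic leucine zipper transcription factor, changes in RNA of sorted epithelial cells. Enterocytes were not sorted apart from other epithelial cells, and nutrient uptake itself was not measured. No group carried Cre without floxed Maf, so effects of Cre itself cannot be told apart from loss of Maf. Maf itself (ENSMUSG00000055435, GRCm38 chromosome 8, 115682942 to 115707794, minus strand) had 9398, 5615 and 3893 counts in the Maf.flox libraries and 16, 1 and 1 in the Vil.Cre Maf.flox libraries. The summed level in Vil.Cre Maf.flox was 0.105% of the control level, with an exact 95% Poisson interval of 0.062 to 0.166% that covers counting error only. Its log2 fold change was -9.89 (SE 0.706, adjusted p = 0.0133, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Maff, Mafg and Mafk, small Maf proteins of the same family, had log2 fold changes of -0.61, -0.53 and -0.19 and did not pass over all genes. Of 5 family members measured, 4 were lower when adjusted over the list alone. Maf itself, whose fall the deletion fixed, was among these.

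Lct, which encodes the lactose-digesting enzyme lactase, fell from 425.8 ± 176 CPM in Maf.flox to 14.7 ± 0.435 CPM in Vil.Cre Maf.flox (SD, n = 3 each). Anpep, an aminopeptidase of the brush border, fell from 5397 ± 1620 to 1048 ± 151 CPM, and Ace, a peptidase of the same membrane, fell from 618.9 ± 280 to 68.05 ± 10.9 CPM (SD, n = 3 each). The peptide transporter Slc15a1 fell from 377.6 ± 163 to 64.46 ± 12.9 CPM and the aromatic amino acid transporter Slc16a10 from 134.3 ± 33.2 to 34.93 ± 4.73 CPM (SD, n = 3 each). On the other side, Zbp1, a sensor of Z-form nucleic acids, rose from 10.45 ± 1.87 to 50.93 ± 13.3 CPM, and Duox2, an epithelial NADPH oxidase, rose from 182.6 ± 12.1 to 555.6 ± 135 CPM (SD, n = 3 each). The metallothionein Mt1 rose from 113.7 ± 17.1 to 373.5 ± 68.7 CPM.

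**Figure D1:**
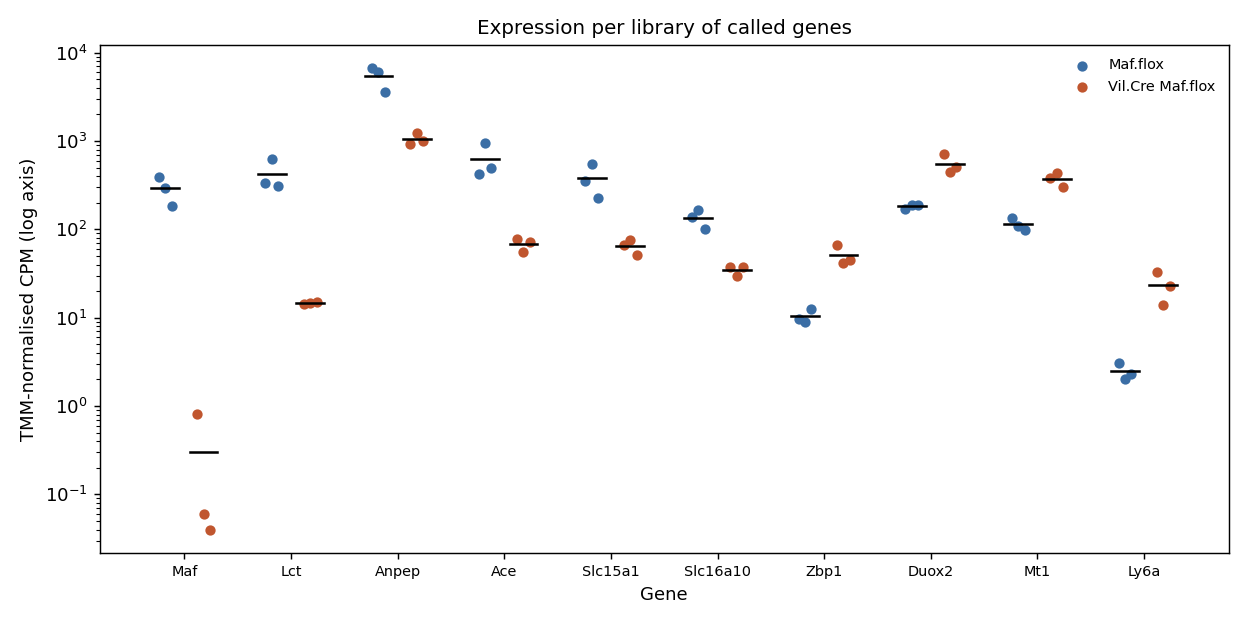
TMM-normalised CPM on a log axis for 10 genes called between the groups, with a point per library and a black line at the mean of the 3 libraries of each genotype. For each gene shown the libraries of the groups did not overlap, which the naming rule required of most of them. The same held for 20.6% of all genes tested. Lct lay at 425.8 CPM on average in Maf.flox and 14.7 CPM in Vil.Cre Maf.flox.

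Across 13740 genes tested, 75 passed an adjusted p of 0.05 by edgeR's quasi-likelihood test, 49 lower and 26 higher in Vil.Cre Maf.flox, and 57 changed at least 2-fold. An unadjusted p under 0.05 by the same test was found for 2248 genes. Members adjusted over a list alone, with no correction across lists, pass more easily against this background. Lct (GRCm38 chromosome 1, 128284756 to 128328318), Zbp1 (chromosome 2, 173206612 to 173218923), Mt1 (chromosome 8, 94179082 to 94180327) and 1810065E05Rik (chromosome 11, 58421111 to 58426024) were called under each of 14 alternative fits at the same threshold, libraries left out in turn included. The other 24 of the 28 named genes called, Maf among them, lost their call in 2 to 8 of these fits, Slc7a15 in 8 and Slc2a2, Slc47a1 and Duoxa2 in 7 each. The number of calls was not stable: it was 38 with sex as a term and ranged from 8 without Vil.Cre Maf.flox replicate 3 to 701 without Maf.flox replicate 3. The excess of lower calls was not stable either, with 8 higher and 4 lower, 16 higher and 7 lower, and 6 higher and 2 lower without Vil.Cre Maf.flox replicate 1, 2 or 3, and 124 higher and 577 lower without Maf.flox replicate 3. Other groupings of the 6 libraries into 3 and 3 gave at most 4 genes. Each of them sets 2 libraries of a genotype against 1, so genotype differences widen the spread within groups and lower this count.

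Among the named genes with the largest falls after Maf, Slc5a12, a sodium-coupled monocarboxylate transporter, had a log2 fold change of -4.97 (SE 0.489), and Lct one of -4.86 (SE 0.302). Slc7a15, Npl and Maob, the last a monoamine oxidase, had log2 fold changes of -4.75, -4.68 and -3.22. They were followed by Ace at -3.18, Rnf208 at -2.93, Slc2a2, the GLUT2 glucose transporter, at -2.93, Plekhf1 at -2.61, the organic cation exporter Slc47a1 at -2.59 and Slc15a1 at -2.55. Slc7a15 and Rnf208 overlap genes on the other strand, and strand use in counting was not stated, so these counts can include reads of the partner. The largest rises were those of Ly6a, a GPI-anchored surface protein, at 3.22 (SE 0.333), the serine protease Prss27 at 2.55, Zbp1 at 2.28, Duoxa2, the maturation factor of Duox2, at 2.11 and 1810065E05Rik at 2.05. Il18bp, which binds interleukin-18, Ifit1bl1, Mt1, Capg, Duox2, Upp1 and 2210407C18Rik had log2 fold changes of 2.02, 1.96, 1.72, 1.68, 1.61, 1.39 and 1.37. Il18bp and Duoxa2 overlap genes on the other strand, and Ly6a and Ifit1bl1 belong to families of similar sequence whose reads counting can split. The adjusted p of these genes lay between 0.00298 and 0.0464 by edgeR's quasi-likelihood test.

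Of the genes of protein digestion and amino acid transport, 22 of 23 measured members had a log2 fold change below 0, with a median of -0.94. Of these members 7 were called lower over all genes and 17 when adjusted over the list alone, and none was called higher. Slc16a10, Anpep, Ace and Slc43a2 had the smallest p, with log2 fold changes of -1.94, -2.36, -3.18 and -1.71; Slc43a2 overlaps an antisense gene and Anpep a predicted gene on its own strand. Of 16 genes of carbohydrate digestion and transport, 15 lay below 0 (median -1.09), Lct and Slc2a2 were called lower over all genes, and 11 were lower adjusted over the list alone. The fructose transporter Slc2a5 had a value of -1.36 and was not called over all genes. With 1 library left out in turn the medians ran from -1.12 to -0.89 for the protein list and from -1.37 to -0.88 for the carbohydrate list. The medians were -1.14 and -0.96 for the protein and carbohydrate lists in males, and -1.02 and -1.22 in females, where each sex has 1 genotype with a single library. Both lists passed camera with a preset correlation (adjusted p = 5.69e-38 and 7.59e-18), and neither passed with an estimated correlation (adjusted p = 0.22 and 0.25). Camera with the preset correlation called 22 of 32 lists here and between 5 and 21 lists in the other groupings of these libraries into 3 and 3, each of which still sets 2 libraries of a genotype against 1.

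Other enterocyte lists had medians below 0 with no member called over all genes. They were lipid uptake and chylomicron assembly (median -0.35, 23 of 27 members below 0), the brush border (-0.51, 14 of 17), retinoid metabolism (-0.84, 9 of 10), xenobiotic metabolism (-0.91, 18 of 20), iron, vitamin and mineral uptake (-0.63, 14 of 16) and the villus tip program (-0.66, 11 of 13). With 1 library left out in turn these medians ran from -0.59 to -0.25, -0.65 to -0.42, -1.10 to -0.56, -1.11 to -0.45, -0.75 to -0.31 and -0.78 to -0.51. Adjusted over the list alone, 3, 8, 6, 6, 3 and 7 of their members were lower, and 1 member each of the retinoid and the iron, vitamin and mineral lists was higher. The villus tip program shares Fos, Fosb, Jun and Junb with the immediate early and heat shock list, whose median was -0.59, and without these genes its median was -0.48. Single members with large values that did not pass over all genes were the fatty acid binding protein Fabp2 at -2.11, the retinol binding protein Rbp2 at -2.39, the intrinsic factor receptor Cubn at -2.22, the scaffold Pdzk1 at -2.12 and Cyp2b10 at -3.53. Enterocyte transcription factors had a median of -0.11, with Creb3l3 at -2.80 and Hnf4g at -0.44, neither called. With an estimated correlation the adjusted p of these 7 lists lay between 0.25 and 0.39.

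Microbial response genes had a log2 fold change above 0 in 11 of 13 measured members (median 1.64). Zbp1, Duox2 and Duoxa2 were called higher over all genes, and 7 members were higher and 1 lower adjusted over the list alone. Zbp1 kept its call in all 14 alternative fits, while Duox2 lost it in 2 and Duoxa2 in 7. The list median was 0.91 without Vil.Cre Maf.flox replicate 1. The antimicrobial lectin genes Reg3b and Reg3g had values of 1.70 and 1.64 with Vil.Cre Maf.flox SDs of 7290 and 3950 CPM on means of 11670 and 5400 CPM, and were not called; as close paralogs they can share reads. Interferon response genes had a median of 0.50, with 3 of 23 called higher over all genes, namely Zbp1, Ifit1bl1 and Bst2, and 8 adjusted over the list alone. With 1 library left out in turn this median ran from 0.37 to 0.70. Zbp1 stands on both lists. The interferon median was 0.03 in males and 0.99 in females, while the microbial response median was 1.29 and 1.27. Each sex has 1 genotype with a single library. The interferon score was 0.68 in Vil.Cre Maf.flox replicate 3, the only female of that genotype, against 0.12 and 0.08 in its males. The interferon contrast can thus rest on that library alone. The adjusted p with an estimated correlation was 0.22 for microbial response and 0.32 for interferon response. The summed immune-marker level was 25.4 ± 5.15 CPM in Maf.flox and 28.9 ± 4.3 CPM in Vil.Cre Maf.flox (SD, n = 3 each), with Lcp1 at 17.45 and 15.99 CPM and Igha at 2.70 and 5.66 CPM.

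**Figure D2:**
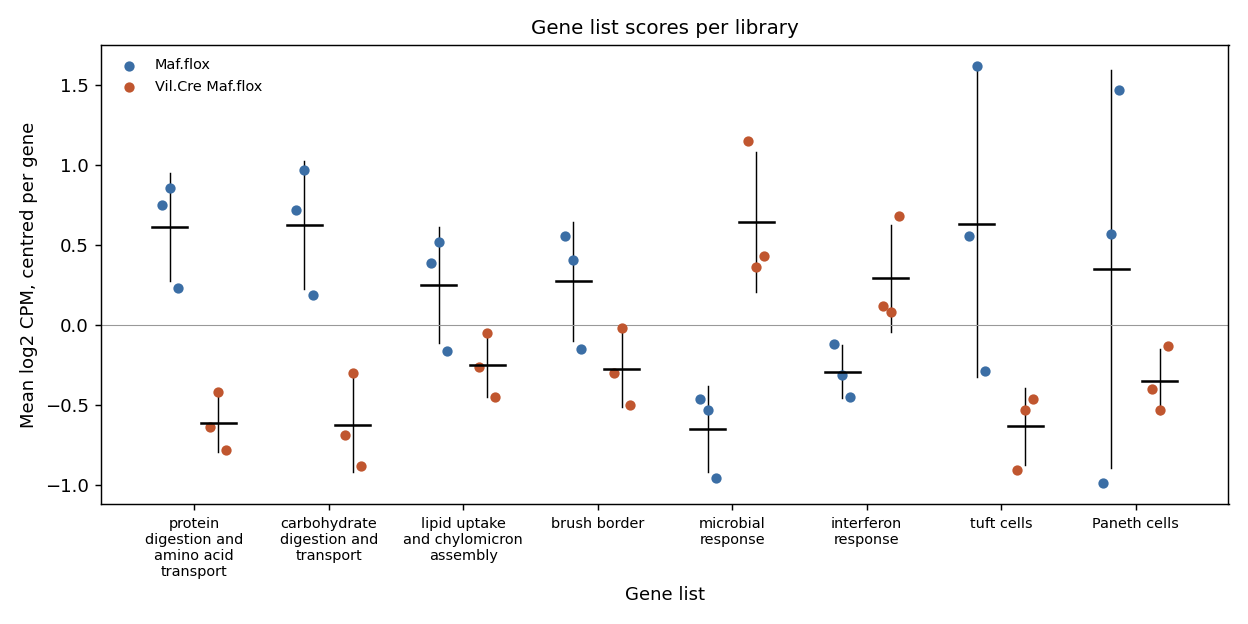
Mean log2 CPM of 8 gene lists per library, centred per gene on the mean of all 6 libraries, with a point per library, a line at each group mean and a bar of 1 SD. The protein and carbohydrate lists lay lower in each Vil.Cre Maf.flox library than in each Maf.flox library, while Paneth scores ran from -0.99 to 1.47 within Maf.flox.

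Among markers of other epithelial cells, the 16 tuft cell genes measured had a median of -1.65, or -0.84 without Maf.flox replicate 2, and all 16 lay below 0. None was called over all genes and 12 were lower adjusted over the list alone, with Alox5ap at -1.87, Ptgs1 at -2.05, Avil at -1.35 and Rgs13 at -1.88 (list adjusted p = 0.32 with an estimated correlation). Tuft scores were 0.56, 1.62 and -0.29 in the Maf.flox libraries and -0.91, -0.53 and -0.46 in the Vil.Cre Maf.flox libraries. Paneth cell genes had a median of -1.09, or -0.44 without Maf.flox replicate 3, with no member called, and their scores overlapped between groups, with Defa17, Defa21 and Defa22 counts also subject to reads shared among defensin copies. Medians were -0.25 for stem cell genes, 0.14 for the cell cycle, 0.06 for goblet cells and -0.24 for enteroendocrine cells, with no member called over all genes in any of these 4 lists. With 1 library left out in turn they ran from -0.39 to -0.10, 0 to 0.27, -0.19 to 0.27 and -0.46 to 0, so that the sign for goblet cells was not fixed.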

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

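The tests here were chosen after the sexes of the libraries had been read from the counts. The genotype difference was compared between males (1 Maf.flox, 2 Vil.Cre Maf.flox) and females (2 and 1) with an interaction term. Each sex has a genotype with a single library, so the spread came from the 2 Maf.flox females and the 2 Vil.Cre Maf.flox males alone (2 residual degrees of freedom), and the test does not separate a difference between the sexes from a deviation of a single library. By edgeR's quasi-likelihood test 0 genes passed at FDR 0.05, and 382 had an unadjusted p under 0.05, fewer than the 687 expected by chance among 13740. With camera's preset correlation 10 of 32 lists passed, and 0 did with an estimated correlation. The adjusted p was 3.8e-37 for Paneth cells (median 0.39 in males, -1.15 in females), 2.3e-13 for interferon response (0.03, 0.99), 2.8e-12 for fatty acid oxidation and PPAR targets (-0.39, 0.14), 6e-08 for xenobiotic metabolism (-1.31, -0.49) and 6e-08 for cytosolic ribosomal proteins (0.19, -0.07). It was 7.4e-06 for goblet cells (-0.05, -0.30), 0.00015 for MHC class II (0.57, 0.02), 0.00038 for enteroendocrine cells (0.01, -0.37), 0.033 for the proximal small intestine (0.22, -0.31) and 0.048 for the unfolded protein response (0.38, 0.24).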

How the results depend on the processing

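The sex term and the other edgeR dispersion settings were chosen after the data were seen. The fall of Maf and the direction of each of the 75 called genes held in every fit that tested them, while the number of calls depended strongly on the fit. Against 75 genes (26 higher, 49 lower, 57 at least 2-fold), there were 365 (151, 214, 164) with no filter and 742 (266, 476, 325) with DESeq2. Limma-voom gave 30 (12, 18, 28), and the sex term gave 38 (15, 23, 30), of which 26 were among the 75. DESeq2 made 15.5% false calls on simulated counts, but these were drawn from edgeR's own dispersion estimates. This rate therefore does not tell whether the further DESeq2 calls are false. FDR 0.01 left 2 genes and FDR 0.1 gave 372. RLE and upper quartile scaling, the stricter filter and the other edgeR settings gave 56 to 103. Leaving out 1 library gave 8 to 701 genes (4 to 124 higher, 2 to 577 lower, 8 to 371 at least 2-fold): 31, 12 and 701 without Maf.flox replicate 1, 2 or 3, and 12, 23 and 8 without Vil.Cre Maf.flox replicate 1, 2 or 3. Lower calls were 65.3% of the 75, but 33.3, 30.4 and 25% without Vil.Cre Maf.flox replicate 1, 2 or 3 and 82.3% without Maf.flox replicate 3. The loss of a library lowers power, but the rise to 701 without Maf.flox replicate 3 went with a wide gap between that library and its group (chi-square per gene 133 and 61.7 against the other controls, 37.8 between these); the cause was not tested. Maf ran from -12.35 to -9.29 in these fits, and its adjusted p by edgeR was 0.0557, 0.0556 and 0.0563 without Maf.flox replicate 2 or Vil.Cre Maf.flox replicate 2 or 3. Of 22 gene lists called with a preset correlation, 0 were called with an estimated correlation and 0 by fry (smallest adjusted p 0.22 and 0.094). A replicate block gave 440 genes (132, 308, 192), which held 71 of the 75. Same-numbered libraries correlated at 0.092, -0.026 and 0.27 in their deviations, so the numbers were not taken as pairs in the main fit. Not every library correlated best with its own number, but the replicate 3 libraries correlated best with each other. Their TMM factors were the highest (1.03 and 1.08) and their rRNA shares the lowest (0.22 and 0.32%). A preparation shared by number is thus neither shown nor excluded. No called gene or list turned direction under any fit. A gene at 1 CPM has 17.5 to 24.8 counts per library, which limits what can be seen below that level.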

Other observations

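In further lists fixed before the data were examined, no member was called over all genes except Lct on the proximal list. Immediate early and heat shock genes had a median of -0.59 (16 of 17 below 0, 7 lower adjusted over the list alone, adjusted p = 0.32 with an estimated correlation), with Btg2 at -0.80, Junb at -0.66 and Fos at -0.77, and BMP signalling genes one of -0.50, with Id2 at -0.60. With 1 library left out in turn these medians ran from -0.77 to -0.34 and from -0.59 to -0.19, and BMP signalling did not pass camera with the preset correlation without Maf.flox replicate 2 or Vil.Cre Maf.flox replicate 3. Nor did BMP signalling pass camera with an estimated correlation (adjusted p = 0.42). Medians were 0.38 for MHC class II, 0.36 for the unfolded protein response (8 members higher and 4 lower adjusted over the list alone), 0.21 for cholesterol synthesis, 0.16 for mitochondrially encoded genes, 0.06 for the villus bottom antimicrobial program and 0.05 for cytosolic ribosomal proteins. With 1 library left out in turn, MHC class II and unfolded protein response medians ran from 0.27 to 0.44 and 0.28 to 0.44. Those of cholesterol synthesis and mitochondrially encoded genes ran from 0.08 to 0.37 and 0.14 to 0.24. Villus bottom and ribosomal medians ran from 0.01 to 0.11 and 0.01 to 0.15, and the former was 0.40 with no filter. The median was -0.10 for fatty acid oxidation and PPAR targets, -0.10 for the proximal small intestine, where the iron exporter Slc40a1 stood at 1.04, and -0.08 for the distal small intestine. With 1 library left out in turn these ran from -0.19 to 0.02, -0.25 to 0.03 and -0.34 to 0. The sign for fatty acid oxidation and for the proximal list was thus not fixed. Of cells the sort excludes, medians were 0.83 for 8 immune genes, 0.34 for 3 stromal, endothelial and neural genes and -0.09 for 3 erythrocyte and acinar genes, each unstable: with 1 library left out in turn they ran from 0.02 to 0.90, 0.08 to 0.78 and -0.53 to 0.05, and the immune median was 0.44 with no filter. Ptprc had 70 counts in Maf.flox (20, 44 and 6 in replicates 1, 2 and 3) and 18 in Vil.Cre Maf.flox (2, 10 and 6).

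Genes outside the naming rule, chosen after their values were seen, included class I antigen processing and interferon-inducible GTPases. All 10 measured had a log2 fold change above 0 and 3 were called by edgeR's quasi-likelihood test: Tap1 at 0.95, Ifi47 at 0.88 and Irgm2 at 1.36, the last overlapping Igtp on its own strand. B2m stood at 0.02. Pck1, an enzyme of gluconeogenesis, stood at -2.50 and was not called (adjusted p = 0.0622 by edgeR). The sodium-proton exchanger Slc9a3 was called higher at 1.06.

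All tests below were chosen after the results they bear on had been seen, except the count of lists over groupings of the libraries. Among the 49 genes called lower, 11 were solute carriers, against a mean of 1.05 and a maximum of 6 in 10000 random sets matched on expression (p = 1e-04, the smallest these permutations can give). Such sets treat genes as independent, which genes that fall together are not, so this p does not measure the spread between libraries. Slc15a1, Slc16a10, Slc43a2, Slc3a2 and Slc2a2 also stand on the protein or carbohydrate lists. Another 2 solute carriers, Slc28a3 and Slc9a3, were called higher. With a library left out the solute carriers among lower calls numbered 4 of 21, 4 of 8 and 41 of 577 without Maf.flox replicate 1, 2 or 3, and 0 of 4, 1 of 7 and 0 of 2 without Vil.Cre Maf.flox replicate 1, 2 or 3, so the count changed with each library left out. Solute carriers may have fallen more often than other genes at their expression level, a hypothesis found and tested on the same data.

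Of protein and carbohydrate digestion genes, 7 of 23 and 2 of 16 were called lower. Fewer enterocytes in the sort would lower all enterocyte lists alike only if their genes were equally confined to enterocytes, which was not measured. These 2 lists lay below the lipid and brush border lists by a further -0.71 on the log2 scale (SE 0.06). They lay below the mean of 6 enterocyte lists, with retinoid, xenobiotic, iron and villus tip genes added, by -0.52 (SE 0.08). From the xenobiotic list alone they did not part (-0.15, SE 0.29). Genes shared with other epithelial cells could also give such gaps, so the gaps do not decide whether fewer enterocytes lowered these 2 lists. Less proximal intestine would lower the proximal list, but not necessarily as far as the median of -1.08 for the protein and carbohydrate lists. Without Lct the proximal median was -0.07 (SD 0.77 over members), a spread that leaves the question open. With sex as a term the difference was -1.32 (SE 0.27), so sex was not the whole cause. A shift in enterocyte maturity or position along the villus, an effect of Cre itself, and an effect of Maf on these genes themselves, remain open.

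Of microbial response and interferon genes, 3 of 13 and 3 of 23 were called higher, Zbp1 on both lists. Immune cells passing the gate would bring their own transcripts. The summed immune markers, at 25.4 CPM in Maf.flox and 28.9 CPM in Vil.Cre Maf.flox, differed by 3.55 CPM (SE 3.87), less than the SE. The rise was 14100 CPM (SE 6000) for the microbial response list and 260 CPM (SE 64.2) for the interferon list. Reg3b and Reg3g, which were not called, made up 11900 CPM of the former (SE 6280), while the called Zbp1, Duox2 and Duoxa2 rose by 491 CPM (SE 101). The lists differ in expression level, and how much of these genes an immune cell would bring was not measured. The sizes of these rises therefore do not decide whether immune cells contributed. With sex as a term the difference was 1.20 (SE 0.32) for microbial response, which sex alone would not give, and 0.64 (SE 0.25) for interferon, against 0.58 (SE 0.22) without the term. The interferon difference was thus not smaller with the term, but its 95% interval on 3 residual degrees of freedom holds 0, so these libraries neither support nor exclude sex for interferon genes. A shared cage or litter, and with it the microbiota, cannot be told apart from genotype, since 0 labels name a cage or litter.

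Tuft cell genes lay below 0 in 16 of 16 members, with 0 called over all genes. Without Maf.flox replicate 2, the library with the highest score, the difference was -0.77 (SE 0.45) against -1.27 (SE 0.57) with it, and with sex as a term it was -1.20 (SE 0.69). Neither a control library rich in tuft cells nor sex can be excluded, and with 3 libraries against 3 an exact permutation test cannot give a p under 0.1.

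The 10 groupings of the 6 libraries into 3 and 3 are too few for a share under 0.05. The genotypes gave 75 genes, and 1 of the 10 groupings, the real one, gave as many; the highest other had 4, in the grouping that follows sex. For genes at least 2-fold changed the values were 57 and 4, and in a single direction 26 higher and 49 lower against at most 3. For gene lists with the preset correlation they were 22 and 21. The other groupings set 2 libraries of a genotype against 1, so their list calls can hold part of the genotype difference. The same mixing widens the spread within groups and lowers their gene counts, which are thus no measure of chance.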
